A study of Nothobranchius furzeri with 20 samples.

How the data were processed

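RNA of the brain was sequenced from 20 samples of male turquoise killifish (Nothobranchius furzeri), a short-lived annual fish, of the wild-derived strain MZM-04/10p. The labels place the samples in 3 groups: 5 fish of 9 weeks without exercise, 5 fish of 9 weeks with exercise in a swim tunnel, and 10 fish of 27 weeks, all labelled as exercised. An unexercised group at 27 weeks was not analysed here. The labels give no batch, tank, duration of exercise or time of sampling. Replicate numbers follow the order in which the samples are listed, so they only name a sample and pair none. No label states that each library came from a different fish. The libraries are called fish here, and the p-values measure only the spread between these libraries.

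The authors deposited raw read counts per gene and RPKM values per gene, each as 1 table of all 20 libraries, and all value columns were matched to samples by title. Libraries were prepared with the TruSeq RNA Library Preparation Kit v2, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4, and give them no role or order. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads shared between near-identical gene copies, overlapping genes or antisense partners can therefore not be told apart, and every gene value carries that limit.

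The deposited counts are whole numbers over 26739 genes, of which 23078 had at least 1 count. They sum to between 15048627 and 34843199 per library, with no entry that names no gene. No 2 replicates of a group were alike within sampling noise, since the lowest chi-square per degree of freedom of any pair was 7.86. Counts were therefore used as deposited, with every library as 1 replicate.

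The deposited RPKM values were checked against the counts. RPKM should be the count divided by gene length and by the total of the same library. Over 10306 genes with at least 200 counts and 1 RPKM, the gene length implied that way varied between libraries with a log2 SD, pooled over genes, of 0.41. With totals of the 20 libraries taken in turn down the table, in place of each library's own total, it varied by 5.49e-05. Only 5.00% of the values were divided by the total of their own library, and the error reached 2.32-fold, with a median of 1.22-fold. RPKM values of a gene are thus not on 1 scale across libraries, and none is reported as a level. A repaired RPKM, with each library's own total put back, served as an alternative. The same relation gave the gene length implied by the deposited values for 23078 genes, with a median of 2356 bp.

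Genes are listed by identifier, and the deposited files do not pair identifiers with names. Of the 26739 identifiers, 0 matched a symbol, locus tag, synonym or accession in the RefSeq table of assembly NfurGRZ-RIMD1. The 36 gene lists fixed before the data were examined, the red blood cell measure and the genes fos, bdnf, gfap, mki67 and fkbp5 were therefore not analysed here. By the rule for named genes, a gene without a symbol is named only if it had the largest rise or the largest fall in a comparison. It also had to pass the threshold, with a mean of at least 1 CPM, the count scaled to the total of its library, in the higher group. This rule names 4 genes over the first 2 comparisons. Genes of the third comparison are counted and not named. No coordinates are given, since the files hold none.

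The designs, the main tests and a first set of alternatives were fixed before the data were examined. Each comparison used edgeR 4.0.16 in R 4.3.3 on the 2 groups compared, with filterByExpr, TMM scaling factors and the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided). Genes with a Benjamini-Hochberg adjusted p below 0.05 passed the threshold, and the adjusted p-values in the text are from this test unless another is named. Log2 fold changes are given with their standard errors. Levels are CPM on the raw library totals, as mean ± SD over fish. No covariate was used, since the labels give none. Before use, each edgeR step was tested on simulated counts with 200 changed genes of at least 1 CPM. Mean levels, totals and the trend of dispersion with mean level were those of the real libraries. The simulated libraries were independent, without an outlying library, a length trend or other shared structure. The false calls given here hold for those conditions and are no error rate for the real libraries. For exercise at 9 weeks (19123 genes) it recovered 43.3% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold, with 11 false calls. For age among exercised fish (19531 genes) it recovered 10.4%, 70.1% and 100%, with 3 false calls. For 27 weeks exercised against 9 weeks unexercised (19591 genes) it recovered 7.46%, 61.2% and 98.5%, with 5 false calls.

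Measures of 1 value per fish were compared with exact two-sided permutation tests over all splits of the fish (252 splits for 5 against 5, 3003 for 5 against 10, 2002 for 5 against 9), adjusted by the Benjamini-Hochberg method within each family. The spread of a fish is the median over 19707 genes of the absolute deviation of its log2 CPM from its group mean, corrected for group size. The length slope of a fish is the slope of its log2 CPM, relative to the mean over all fish, on log2 gene length. The overlap of effects between comparisons that share libraries was set against 1000 simulated draws in which no group differed, and recomputed with the 5 shared libraries split into 2 and 3 between the comparisons, in all 10 ways and both ways round. The code for these measures passed 10 of 10 checks on simulated values over 4000 genes.

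The alternatives were relative log expression factors, upper quartile factors, no expression filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma 3.58.1 on log2 of the deposited RPKM plus 1 or plus 0.1, robust dispersion, all 20 libraries in the fit, removal of the 10 most counted genes, and leaving out each replicate in turn. Alternatives added after the data were seen were limma on the repaired RPKM, removal of a length trend from each library (a spline of 5 degrees of freedom), limma-voom with library quality weights, the first residual component as a covariate, and refits without replicate 8 of the 27-week group. Python 3.11.15 was used for the other steps.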

Results

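Gene expression was measured by RNA-seq in the brain of male turquoise killifish of the strain MZM-04/10p, at 9 and 27 weeks of age, after swim tunnel exercise or without it. The groups were 5 unexercised fish of 9 weeks, 5 exercised fish of 9 weeks and 10 fish of 27 weeks that were all labelled as exercised. Counts per library summed to 26326084 ± 3612040 (SD, n = 5) in the unexercised 9-week group, 21288176 ± 7831296 (n = 5) in the exercised 9-week group and 24058832 ± 3087113 (n = 10) in the 27-week group, with a range of 15048627 to 34843199. Between 21440 and 22032 genes had counts in a library. For total counts, genes detected and the share of the 10 most counted genes, none of the 9 differences between groups passed an exact permutation test, two-sided, with adjusted p from 0.536 to 0.992. Genes are given by their deposited identifiers, because the files pair these with no names.

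Replicate 8 of the 27-week group stood apart from the other 19 libraries. It had 880 genes at least 4-fold above the mean of the other libraries, against 197 in replicate 4 of the same group, the next highest. These 880 genes held 25.7% of its counts. Its 10 most counted genes took 10.4% of all counts, against 3.05% to 3.72% in the other libraries. The library entered every comparison of 27-week fish, and counts without it are given beside each.

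**Figure D1:**
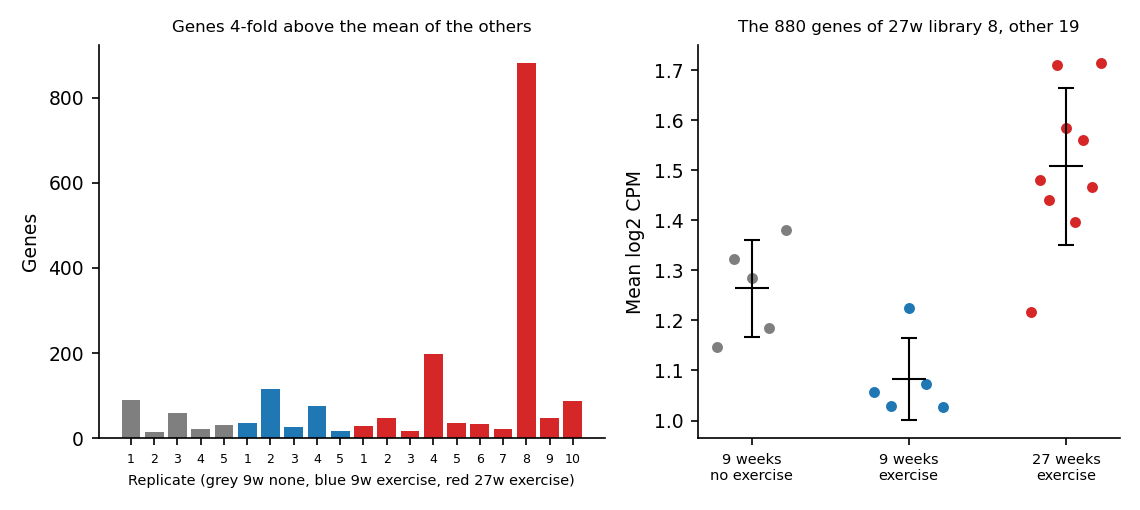
The left panel shows, for each of the 20 libraries, the number of genes at least 4-fold above the mean of the other libraries, with 880 in replicate 8 of the 27-week group. The right panel shows the mean log2 CPM of those 880 genes in each of the other 19 libraries, with the group mean and SD as horizontal line and error bar (1.26 ± 0.0970 unexercised and 1.08 ± 0.0822 exercised at 9 weeks, 1.51 ± 0.157 at 27 weeks).

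The first comparison asked how exercise changed brain expression at 9 weeks. A small set of genes differed, and most of them were lower in exercised fish. Of 19123 genes tested, 19 passed the threshold, of which 15 fell and 4 rose. The median size of the 19 changes was 0.93 on the log2 scale, and 8 exceeded 2-fold, 7 of them falls. Among the 19 genes, Nfu_g_1_003916 had the largest rise, from 5.74 ± 0.730 CPM (SD, n = 5) in unexercised to 11.7 ± 1.15 CPM (n = 5) in exercised fish (log2 fold change 1.01, SE 0.11, edgeR adjusted p = 0.0165, higher in 5 of 5 exercised fish). Nfu_g_1_011166 had the largest fall among the 19, from 28.0 ± 6.54 CPM to 9.22 ± 1.79 CPM (log2 fold change -1.62, SE 0.18, edgeR adjusted p = 0.0165, lower in 5 of 5 exercised fish).

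Before adjustment 2316 genes had p below 0.05 in the edgeR test, where 956 would do so by chance among fish without shared structure. Such a structure was present, since another split of these fish, across the groups, gave 1023 genes past the threshold (see other observations). Neither this excess nor the count of 19 therefore excludes chance. The count of 19 rested on single libraries: it was 4, 10 and 9 without unexercised replicates 2, 4 and 5, and 10, 7 and 0 without exercised replicates 1, 2 and 3, with 2119 genes at an unadjusted p below 0.05 in the last of these edgeR fits and an adjusted p of 0.0740 for both named genes. In that fit the log2 fold changes were 0.976 for Nfu_g_1_003916 and -1.55 for Nfu_g_1_011166. DESeq2 called 353 genes (155 higher, 198 lower), limma on the deposited RPKM plus 1 called 21 (0 higher, 4 of them among the 19), and edgeR with all 20 libraries in the fit called 1. Limma on the deposited RPKM plus 0.1 called 34, edgeR called 9 with the length trend removed and 29 with the first residual component as a covariate.

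**Figure D2:**
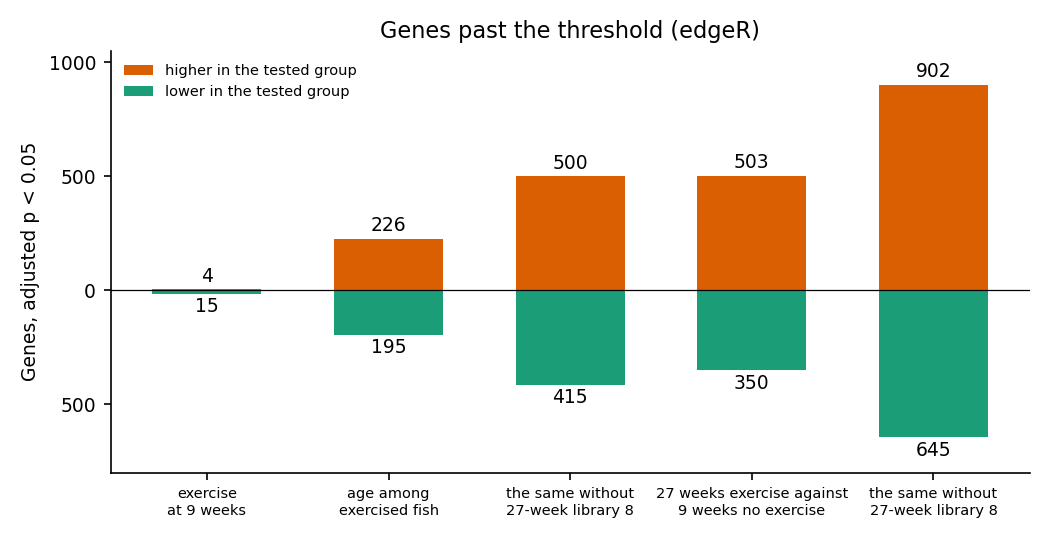
Bars show the number of genes past the edgeR threshold in each comparison, higher in the tested group above the line and lower below it. The exercise comparison had 19 such genes and the age comparison 421, or 915 without replicate 8 of the 27-week group.

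The second comparison asked how the brain of exercised fish differed between 9 and 27 weeks. Of 19531 genes tested, 421 passed the threshold, 226 higher and 195 lower at 27 weeks. Most of these changes were small, with a median size of 0.39 on the log2 scale, and 58 exceeded 2-fold, 52 of them rises. Without replicate 8 of the 27-week group 128 exceeded 2-fold, 123 of them rises. Among called genes with a mean of at least 1 CPM in the higher group, Nfu_g_1_001318 had the largest rise. It went from 0.0574 ± 0.0411 CPM (SD, n = 5) at 9 weeks, or 0 to 4 counts per library, to 1.28 ± 1.27 CPM (n = 10) at 27 weeks, or 1 to 89 counts (log2 fold change 4.30, SE 1.03, edgeR adjusted p = 0.0436, above all 5 exercised 9-week fish in 9 of 10 fish). In unexercised 9-week fish it stood at 0.0790 ± 0.0626 CPM (n = 5). Within the same limits, Nfu_g_1_003210 had the largest fall, from 14.8 ± 2.99 CPM (n = 5) to 5.78 ± 1.87 CPM (n = 10; log2 fold change -1.34, SE 0.19, edgeR adjusted p = 0.0104, lower in 10 of 10 fish), with 7.95 ± 1.25 CPM (n = 5) in unexercised 9-week fish.

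The genes named for exercise differed in their behaviour with age. Nfu_g_1_003916 was lower at 27 weeks, at 5.56 ± 0.984 CPM (SD, n = 10; log2 fold change -1.06, SE 0.10, edgeR adjusted p = 0.000104, lower in 10 of 10 fish). Nfu_g_1_011166 ranged from 2.48 to 47.3 CPM among the 27-week fish, with a mean of 21.0 ± 19.4 CPM (n = 10), and did not pass the age test (log2 fold change 1.28, SE 0.82, edgeR adjusted p = 0.365).

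**Figure D3:**
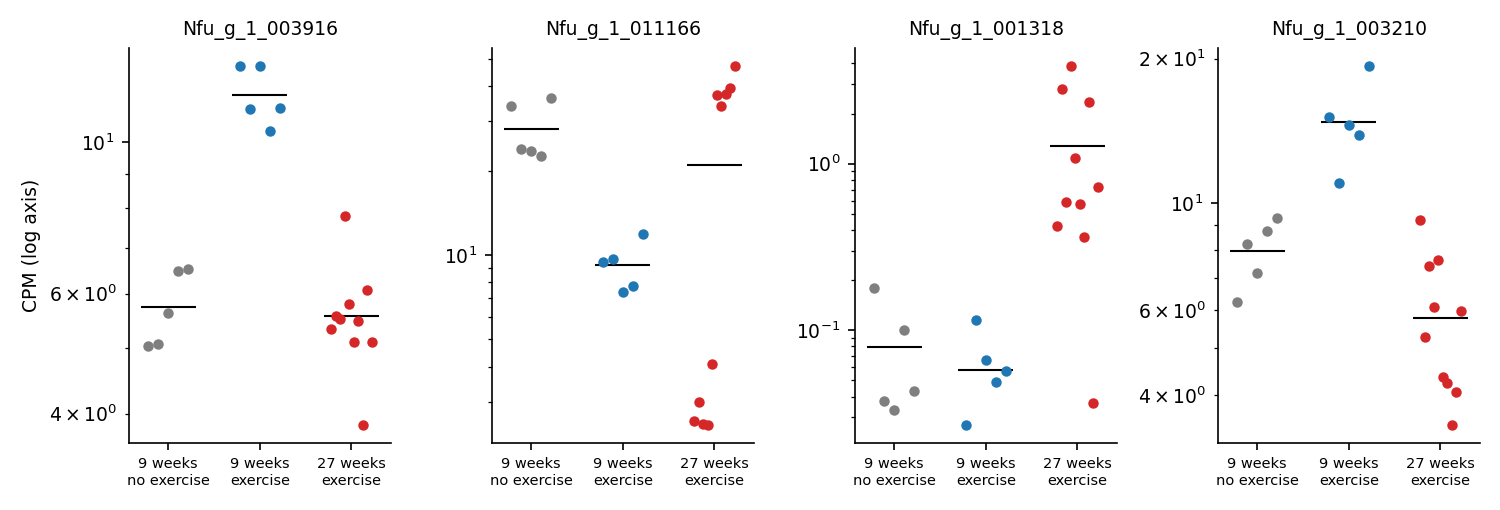
Points show the CPM of each fish on a log axis for the 4 named genes, with the group mean as a horizontal line, and the 1 library with a count of 0 for Nfu_g_1_001318 is drawn at the level of 0.5 counts (0.0271 CPM). Nfu_g_1_011166 spans 2.48 to 47.3 CPM among the 10 fish of 27 weeks.

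In the age comparison 4407 genes had an unadjusted p below 0.05 in the edgeR test, where 977 would do so by chance among fish without shared structure. Single libraries moved the count of 421: without exercised 9-week replicates 1 to 5 it was 102, 44, 137, 7 and 169, without 27-week replicates 2, 5 and 6 it was 187, 194 and 720, and without replicate 8 it was 915 (500 higher, 415 lower). Limma on the repaired RPKM, which differs in the test as well as the scale, called 57 genes higher and 13 lower at plus 1 (81.4% rises) and 70 and 11 at plus 0.1 (86.4%), against 53.7% rises in edgeR. DESeq2 called 1688 genes, limma-voom with library weights 1568, edgeR with all 20 libraries 1207 and with the first residual component 2442, while limma on the deposited RPKM called 2 at plus 1 and 11 at plus 0.1. The call for Nfu_g_1_001318 was lost without any 1 of the 5 exercised 9-week replicates, at edgeR adjusted p from 0.0849 to 0.136, and without 27-week replicate 2, 4 or 5, at 0.0675, 0.0563 and 0.0676. Its log2 fold change lay between 3.98 and 4.83 whichever replicate was left out. On the log2 scale of RPKM plus a pseudocount, which understates changes of low genes, limma gave 0.44 (deposited) and 0.46 (repaired) at plus 1 and 1.79 and 1.81 at plus 0.1, and none of these passed (adjusted p from 0.123 to 0.491).

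Among exercised fish, fold changes with age followed gene length. The measures of this trend were chosen after the data were seen. The median log2 fold change from 9 to 27 weeks was 0.05 for the 2498 genes shorter than 800 bp and -0.11 for the 857 genes of 9000 bp or more, or 0.02 and -0.09 without replicate 8 of the 27-week group. Genes that rose had a median length of 2422 bp and genes that fell one of 4543 bp. The length slope averaged 0.0133 ± 0.00987 log2 CPM per doubling of length (SD, n = 5) in exercised 9-week fish and -0.00896 ± 0.0193 (n = 10) in 27-week fish, a difference of -0.0223 (exact permutation p = 0.0173, two-sided, adjusted p = 0.0433 over 5 slope tests). Without replicate 8 the 27-week mean was -0.00326 ± 0.00741 (n = 9) and the difference -0.0166 (exact permutation adjusted p = 0.0200). In unexercised 9-week fish the mean was 0.00461 ± 0.00761 (n = 5), and its difference from exercised 9-week fish did not pass (exact permutation adjusted p = 0.190). The slope of 27-week fish differed from that of unexercised 9-week fish by -0.0136 (exact permutation adjusted p = 0.177), or by -0.00787 without replicate 8 (exact permutation adjusted p = 0.146), and neither slope difference passed. A second measure, the median of genes of 6000 bp or more minus that of genes below 1500 bp, differed from unexercised 9-week fish by -0.08 on the log2 scale (exact permutation adjusted p = 0.0529) and without replicate 8 by -0.06, which passed (exact permutation adjusted p = 0.0433). Against exercised 9-week fish it differed by -0.11, and by -0.09 without replicate 8 (exact permutation adjusted p = 0.0266 for both). With the length trend of each library removed, edgeR called 156 genes in the age comparison, 64 higher and 92 lower, so the share of rises was 41.0% in place of 53.7%. Without replicate 8 it called 617, with 43.1% rises in place of 54.6%.

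**Figure D4:**
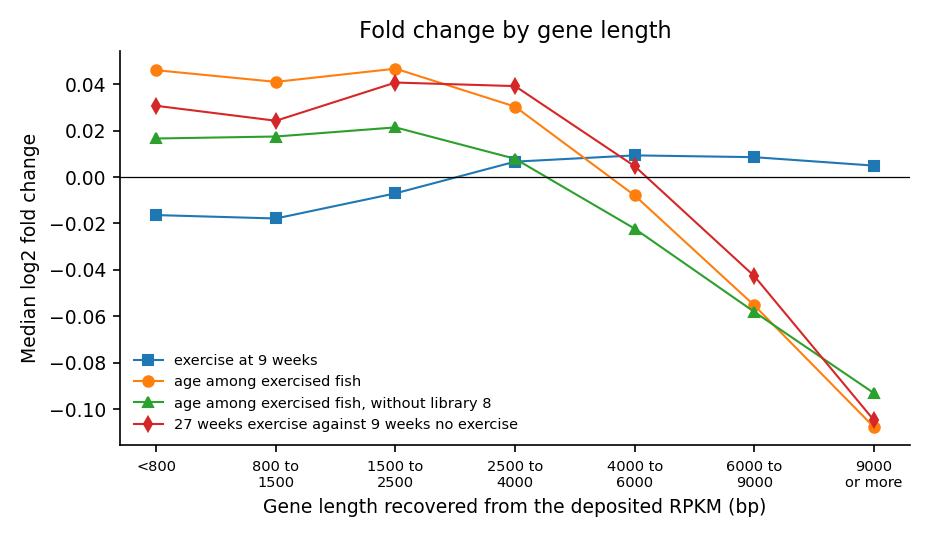
Lines show the median log2 fold change of the genes in 7 bins of gene length (bp), for each comparison and for the age comparison without replicate 8 of the 27-week group. In the age comparison the median runs from 0.05 below 800 bp to -0.11 at 9000 bp or more, and without replicate 8 from 0.02 to -0.09.

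The third comparison set the 27-week fish, labelled as exercised, against unexercised 9-week fish, so age and exercise both differed. Of 19591 genes tested, 853 passed the threshold, 503 higher and 350 lower at 27 weeks. The median size was 0.41 on the log2 scale and 122 changes exceeded 2-fold (106 rises), or 168 without replicate 8 of the 27-week group. Nfu_g_1_001318 was also higher in this comparison (log2 fold change 4.03, SE 0.97, edgeR adjusted p = 0.0347, above all 5 unexercised fish in 9 of 10 fish), while Nfu_g_1_003210 did not pass (log2 fold change -0.47, SE 0.19, edgeR adjusted p = 0.140) and neither did Nfu_g_1_003916 (log2 fold change -0.05, SE 0.11, edgeR adjusted p = 0.818).

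Here 4950 genes had an unadjusted p below 0.05 in the edgeR test, where 980 would do so by chance among fish without shared structure. Without unexercised replicates 1 to 5 the count of 853 was 147, 249, 317, 175 and 177, without 27-week replicates 1, 2, 3 and 5 it was 538, 508, 553 and 339, and without replicate 8 it was 1547 (902 higher, 645 lower). With the length trend removed edgeR called 365 genes, with 47.1% rises in place of 59.0%, while limma on the repaired RPKM gave 67.6% rises at plus 1 and 73.6% at plus 0.1. DESeq2 called 2323 genes, limma-voom with library weights 2637, edgeR with all 20 libraries 1793 and with the first residual component 2874, while limma on the deposited RPKM called 7 at plus 1 and 8 at plus 0.1.

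Of the genes called in the comparisons of 27-week fish with either 9-week group, 107 were higher in both and 90 lower in both, and 0 went opposite ways among 19092 genes tested in all comparisons. Independent lists of those sizes would share 5.64 and 3.54, but both comparisons contain the same 10 fish of 27 weeks, which adds to the overlap. Of the 4 genes that rose with exercise, 3 were lower at 27 weeks among exercised fish (0.0406 for independent lists), and of the 15 that fell, 1 was higher (0.174). The exercised 9-week libraries are in both of these comparisons with opposite sign. The log2 fold changes of exercise and of age correlated across 19707 genes at -0.38, with a covariance of -0.0408. Simulated groups without any effect gave a mean correlation of -0.49 (-0.84 to 0.01) and a mean covariance of -0.0292 (-0.0878 to 0.000299), so the observed values lay within the range given by the shared libraries alone. With the shared libraries split between the comparisons the mean covariance was -0.0104 (-0.0321 to 0.0369 over 20 draws), or -0.00575 (-0.0260 to 0.0356) without replicate 8 of the 27-week group. Exercise and the third comparison share the unexercised libraries with the same sign. Their covariance was 0.0461, within the -0.000364 to 0.0841 of simulated groups without any effect, which averaged 0.0272. With those libraries split it was 0.0191 (-0.00974 to 0.0353 over 20 draws), and without replicate 8 it was 0.0237, with all draws above 0 (0.00435 to 0.0381). The draws reuse the same fish, so their range is no test.

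The 27-week fish lay further from the mean of their group than the 9-week fish did from theirs. The median absolute deviation of a fish from its group was 0.174 ± 0.0488 log2 CPM (SD, n = 10) at 27 weeks, 0.123 ± 0.00464 (n = 5) in exercised and 0.118 ± 0.0101 (n = 5) in unexercised 9-week fish. The difference was 0.0509 against exercised fish (exact permutation p = 0.0200, two-sided) and 0.0562 against unexercised fish (p = 0.0123), with an adjusted p of 0.0200 for both. Without replicate 8 the 27-week value was 0.153 ± 0.0232 (n = 9), and the differences were 0.0293 (exact permutation p = 0.0160) and 0.0346 (p = 0.0105). With the mean over genes in place of the median the differences were 0.0670 and 0.0842 and did not pass (exact permutation p = 0.172 and 0.0763). Against exercised fish the difference was 0.0485 without exercised replicate 1 and 0.0492 without replicate 3, at exact permutation p of 0.0629 and 0.0579. The 27-week fish parted by listing order, as described under other observations, which can add to their distance from 1 common mean. How much it added was not tested. Fish of a group share that mean, so their values are not independent, although the permutation treats them as such.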

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

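Every test in this part was chosen after the result was seen. In each group of 4 to 10 fish, the gap between the highest or lowest value and its nearest neighbour was set against the range of the group. A fish stood apart in 8 of 33 such groups of values, where chance gives about 1 in 20, but 5 of the 8 were replicate 8 of the 27-week group on related measures. Exercised 9-week replicate 2 had 34843199 counts and 22032 genes detected, both the highest of its group. Replicate 8 of the 27-week group had 10.4% of its counts in the 10 most counted genes, a TMM factor of 0.731, a length slope of -0.0603, a spread of 0.303 and a mean log2 CPM of 5.60 over its own 880 raised genes, the last of which is fixed by the choice of those genes. Exercised 9-week replicate 3 had a mean log2 CPM of 1.23 over the same genes, the highest of its group.

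Replicate 8 of the 27-week group differed from the other 19 libraries in 880 genes at least 4-fold above and 296 at least 4-fold below their mean, where the next highest library had 197 above and no other had as many below. Gene length as the whole cause is argued against, since 778 genes stayed 4-fold above with the length trend removed (191 in the next library). Without the 10 genes most counted over all libraries 878 stayed (198 in the next library). That count cannot test a few dominant genes as the cause. The TMM factors already allow for such genes, and dominant genes would lower the share of the others rather than raise it. RNA of another tissue mixed in stays open: 28.5% of the genes above had under 1 CPM in the other libraries, against 8.77% of all genes, and a profile of another tissue to set against the genes below was not used here. Without gene names the source cannot be told apart from a change in that brain, and no biological explanation was tested.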

How the results depend on the processing

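The alternatives for RPKM as deposited, DESeq2, all 20 libraries, filters, scaling factors and single replicates were planned; the repaired RPKM, length trend, voom, residual component and refits without replicate 8 together with another change were chosen after seeing the data. Where a value moved, the cause was not tested. No paired analysis was possible because the labels number no replicates. The planned gene list tests were not run, since no gene name was matched.

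Exercise at 9 weeks gave 19 genes. Leaving out 1 replicate gave 0 to 15 (4, 10 and 9 without unexercised 2, 4 and 5; 10, 7 and 0 without exercised 1, 2 and 3, the last with edgeR and 2119 genes at unadjusted p below 0.05). DESeq2 gave 353, with 43.9% rises against 21.1%, limma on deposited RPKM plus 0.1 gave 34 (2 higher, 5 shared with the 19), the fit of all 20 libraries 1, the fit of the other 19 without replicate 8 gave 2, length trend removal 9 and the residual component 29. The deposited RPKM moved the median of all genes by -0.25 (plus 1) and -0.34 (plus 0.1) on the log2 scale here, and by up to 0.20 in the age comparison. The other 14 settings stayed within 1.5 times, but 1 of them, limma on deposited RPKM plus 1, gave 21 genes with 0 higher and shared 4 with the 19.

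Age among exercised fish gave 421 genes. Leaving out 1 replicate gave 7 to 915 (102, 44, 137, 7 and 169 without exercised 9-week 1 to 5; 187, 194, 720 and 915 without 27-week 2, 5, 6 and 8). DESeq2 gave 1688, RPKM plus 1 and plus 0.1 gave 2 and 11, all 20 libraries 1207, repaired RPKM 70 and 81, length trend removal 156, voom with weights 1568 and the residual component 2442. Without replicate 8 the residual component gave 1482, DESeq2 1871, RPKM plus 1 gave 45 and repaired RPKM 874. Rises made up 81.4% and 86.4% of the calls with repaired RPKM plus 1 and plus 0.1, against 53.7%, and 68.5% with plus 1 against 54.6% without replicate 8. The other 13 settings stayed within 1.5 times.

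The third comparison gave 853 genes. Leaving out 1 replicate gave 147 to 1547 (147, 249, 317, 175 and 177 without unexercised 1 to 5; 538, 508, 553, 339 and 1547 without 27-week 1, 2, 3, 5 and 8). DESeq2 gave 2323, RPKM 7 and 8, all 20 libraries 1793, repaired RPKM 136.0 and 159, length trend removal 365, voom 2637 and the residual component 2874. Without replicate 8 the residual component gave 2376, DESeq2 2623, RPKM plus 1 gave 15 and repaired RPKM 1561, with 72.2% rises against 58.3%. The other 12 settings stayed within 1.5 times.

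The difference in spread ranged from 0.0293 to 0.0566 against exercised and from 0.0346 to 0.0618 against unexercised 9-week fish when 1 replicate was left out. It was lost with the mean over genes (0.0670, exact permutation p = 0.172, and 0.0842, p = 0.0763) and, against exercised fish, without exercised replicates 1 (p = 0.0629) and 3 (p = 0.0579).

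No named gene changed direction. Nfu_g_1_003916 and Nfu_g_1_011166 lost their call in 3 and 4 of 26 settings, the latter at edgeR adjusted p = 0.875 with all 20 libraries in the fit but at a log2 fold change of -1.62 as before, as Nfu_g_1_003210 did in 2 of 35 and Nfu_g_1_001318, with 0 to 4 counts per exercised 9-week library, in 15 of 34, and the filter of 1 CPM in 5 libraries left it untested.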

Other observations

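The splits of the fish into other groups were planned before their results were seen; the other tests in this part were chosen after. The 880 genes raised in replicate 8 of the 27-week group also differed between the groups among the other 19 libraries. Their mean log2 CPM was 1.26 ± 0.0970 (SD, n = 5) in unexercised 9-week fish, 1.08 ± 0.0822 (n = 5) in exercised 9-week fish and 1.51 ± 0.157 (n = 9) at 27 weeks. The rise of 0.43 with age among exercised fish (exact permutation adjusted p = 0.0030, 77.6% of the genes higher) held in all 7 other choices of gene set and scale, and the median gene rose by 0.29, where 10000 random lists matched on mean expression gave -0.03 to 0.06. Replicate 8 is itself a 27-week fish, so choosing genes by it favours genes that are higher at 27 weeks. The random lists were not matched on that. Neither comparison of 27-week fish is therefore a test of these genes as a set. The fall of 0.18 with exercise (adjusted p = 0.0238, exact permutation) was lost in 3 of 7. It was -0.16 with the length trend removed (exact permutation adjusted p = 0.0556), and over the 582 genes under 100 CPM in replicate 8 it was -0.04 (0.452), or -0.02 with the trend removed (0.762). The difference of 0.24 between 27-week and unexercised 9-week fish (exact permutation adjusted p = 0.0165) was lost in 2 of 7, both over the 335 genes at least 16-fold above, where it was 0.23 (adjusted p = 0.0989, exact permutation) and 0.22 with the trend removed (0.0924). Reads carried over from replicate 8 would put a fixed share of its counts into each library. Of 146 highly counted genes, more than 1 in 20 lay more than 4-fold below the median share in 17 of the 19 libraries, which such a share alone would not give, while 27-week replicates 2 and 9 had 0 and 6 such genes. The shares include each library's own expression, so carry-over as a part of the rise with age is not excluded. The 5th percentile of the shares was 0.0382% to 0.211% in the 27-week libraries and 0.0136% to 0.0650% in the 9-week ones.

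Among the 15 genes that fell with exercise at 9 weeks, the 27-week fish parted widely. In 10 of the 15 the largest gap between neighbouring fish lay at the same place, with 5 fish on either side and gaps of 0.65 to 3.50 on the log2 scale. In all 10 genes replicates 1 to 5 were the lower fish, so the parting follows the order in which the samples are listed. The sample titles number these 5 in an unbroken run, with a gap in the numbering before the other 5. Gaps also lie between the 9-week groups, within the unexercised 9-week group and within the other 5, so this gap is not singular. No label states what the numbering or its gaps stand for. The median SD of the 15 genes among 27-week fish was 0.98, where 10000 random lists matched on mean expression gave 0.11 to 0.48. The parting was not confined to these genes. With replicate 8 left out, principal component 2, an axis of variation shared by many genes, held 15.6% of the variance. On it the 27-week replicates 1 to 5 lay at 20.6 to 39.5, and replicates 6, 7, 9 and 10 at -5.46 to 0.407. The 9-week fish lay at -21.3 to -0.541. For Nfu_g_1_011166 the 27-week replicates 1 to 10 stood at 2.57, 3.00, 2.51, 2.48, 4.08, 37.3, 33.9, 37.5, 39.5 and 47.3 CPM, where unexercised 9-week fish ranged from 22.6 to 36.3 and exercised ones from 7.38 to 11.9 CPM.

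Replicate 8 alone does not make this pattern, as it was set apart in 2 of the 15 genes. The median fold across the largest gap, over all 15 genes, was 2.60, and the largest 27-week total was 1.48 times the smallest. The gene values were already scaled for library size, so this comparison cannot test it. A candidate explanation is that the 27-week fish were not all treated alike or carry a wrong label. It is open: 10 of the 15 lowered genes part at 1 place, but 0 of the 4 raised genes do, and Nfu_g_1_003916 lay between 3.85 and 7.79 CPM in all 10 fish, below the 10.4 to 13.0 CPM of exercised 9-week fish. A wrong label cannot be told apart from another factor, because the labels give no unexercised fish at 27 weeks and no tank or time of sampling. A difference between old fish in their response to exercise stays open too, as untested.

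The trend of age changes with gene length may be technical, such as a difference in RNA quality, or may reflect age. Replicate 8 is not its source, since the difference in slope among exercised fish held without it (exact permutation adjusted p = 0.0200). The slope also followed the listing order of the 27-week fish. It was -0.00178 to 0.00363 in replicates 1 to 5 and -0.0603 to -0.00182 in replicates 6 to 10. Both ranges lay below the mean of 0.0133 in exercised 9-week fish. The difference between long and short genes overlapped, at -0.0715 to 0.0210 and -0.247 to -0.00672. As the whole cause of the 421 calls the trend is argued against by the 148 genes, or 35.2%, that stayed past the edgeR threshold once it was removed, and without replicate 8 by 549 of 915, or 60.0%. All 421 kept their sign, but 162 rises and 111 falls lost their call: the median size of these rises went from 0.41 to 0.35 on the log2 scale (median SE 0.09 before, 0.10 after) and that of these falls was 0.32 before and after (SE 0.07, then 0.08). The largest unadjusted p that passed went from 0.00108 to 0.000396 in edgeR, and 49 of these rises and 58 of these falls would still have met the first. RNA quality was not given in the labels, so for the trend itself a technical source and age were not separated. Neither was separated from whatever parts the 27-week fish by listing order.

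For the test of other splits of the same fish, the real split and others drawn at random made up 100 per comparison, not all possible splits. As many genes as the 19 of exercise came from 3 of the 100, the real one included. That is under the share of 0.05 fixed beforehand. One other split gave 1023 genes, with exercised replicates 1, 3 and 5 and unexercised replicates 2 and 5 on 1 side, and a similar one gave 393. A split with many times the real count points to a structure among the 9-week fish that crosses the groups and that no label names. With such a structure present, the splits cannot exclude chance for the 19 genes. For age among exercised fish 1 of 100 splits, the real one, gave 421 genes, and the highest other gave 276. Of the 20 other splits with any call, 18 had replicate 8 among the 5 fish set apart. Without replicate 8 the real split gave 915 and the highest other 6 (1 of 100). For the third comparison 1 of 100 splits, the real one, gave 853, and the highest other gave 376. In the age comparison, with or without replicate 8, and in the third, no other split reached the real count, which argues against chance there.

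A score built from the 100 genes that best parted the other 9-week fish, with 0 at the unexercised and 1 at the exercised mean, gave a left-out fish 0.420 ± 0.122 (SD, n = 5) if unexercised and 0.571 ± 0.295 (n = 5) if exercised. The ranges of 0.258 to 0.591 and 0.182 to 0.945 overlapped. Among 27-week fish, replicates 1 to 5 scored 0.444 to 0.749 and replicates 6 to 10 scored -1.60 (replicate 8) to 0.387. The score thus also followed their order of listing. Since it did not part left-out 9-week fish, it cannot show which 27-week fish were exercised.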
